A study of Petunia x hybrida with 9 samples.

How the data were processed

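Corolla RNA of 3 petunia genotypes, 3 libraries each, was sequenced on an Illumina HiSeq instrument, per the series' design text. The submitters' processing notes name FastQC 0.11.2 and Bowtie2 2.2.6; the assembler, the program that computed the expression values and any scaling between libraries are not given in the sources used here. Expression was deposited by the authors as FPKM, fragments per kilobase of locus scaled by the fragments of the library, with a column per library. A separate table deposited by the authors gives, per the file headers, the best tomato protein of a locus with its identity in percent, bit score, e-value (at most 0.001) and description. A median identity of 82.46 percent means that a name is that of the closest tomato protein, not of a petunia gene. The label naming the mutation R353A stands on all samples, wild type included, and was not used to group them. No reference genome was used, so positions are not given.

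Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate plants, so p-values measure the spread between these samples, which may be technical. No library was a copy of another. Depth was estimated from low values of loci between 700 and 2000 bases long: 100% of the values used, up to about 4 fragments, lay within 0.1 of a whole multiple of the worth of 1 fragment. Loci with no value above 0 were more frequent in wild type (2042, 1881 and 2078 loci) than in the libraries labelled A4 (633, 976 and 753) or A9 (1016, 888 and 1147). Loci without a tomato match held between 7.46% and 7.70% of the summed FPKM in wild type and between 9.45% and 9.78% in the other libraries. Because the values are FPKM and not counts, no count model was run.

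The tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Loci with a mean of at least 1 FPKM over the 9 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, in a single fit of 3 group means with a trended variance prior, and called at a Benjamini-Hochberg adjusted p under 0.05. Changes are given with their standard errors. The contrasts were each line against wild type, the mean of both lines against wild type, and A4 against A9. The 27 gene lists were word patterns, and a locus belonged to a list when the pattern matched the protein name of its tomato hit. Matching the name and not the full description was settled after the descriptions had been seen. Some names matched by chance of a word. Without those, 79 of 88 measured loci remain in the shikimate list, 236 of 263 in ethylene and 91 of 102 in jasmonate. In the cell wall list 207 of 219 remain, and in ribosomal proteins 713 of 738. The counts printed below use the lists with these matches. Lists with at least 3 measured loci were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with camera at an estimated correlation and fry as alternatives. None of the camera calls held with an estimated correlation, which gave 0, 4, 1 and 1 lists an unadjusted p under 0.05 for A4 with wild type, A9 with wild type, the mean of both lines and A4 with A9; fry called 8, 12, 13 and 4 lists. The summed FPKM of the dehydratase loci was compared with an exact two-sided permutation test.

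Named loci followed a rule. It took every measured locus described as arogenate or prephenate dehydratase. For each line against wild type it took the 10 largest rises and 10 largest falls past the threshold. These needed a mean of at least 5 FPKM, no overlap between libraries of the groups, a hit with an e-value of at most 1e-10 and an informative description, and only the first locus of a given hit or description was kept. It took the 4 members of each list with the lowest p for the mean of both lines, and the 5 highest and 5 lowest loci for A4 against A9. Not all loci it took are printed. Loci named outside it are marked as such.

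Replicate numbers are shared by the groups. For each pair of groups the deviations of same-numbered libraries from their group means were correlated across loci. All 3 correlations were above 0.1 for wild type with A9 (0.248, 0.344 and 0.104) and for A4 with A9 (0.240, 0.261 and 0.249), so the numbers were taken to pair the samples there. They were 0.229, 0.192 and -0.125 for wild type with A4, and the numbers were not taken to pair those. The pairing comes from this check alone, since the labels name no shared day or batch. It is not coherent, since pairing wild type and A4 each with A9 would also pair them with each other. The third principal component of log2(FPKM + 1), with 6.9% of the variance, ranked the replicates alike in all 3 groups. For replicates 1, 2 and 3 it was 18.62, -30.49 and 11.79 in wild type and 35, -15.4 and -4.67 in A4. In A9 it was 17, -37.99 and 6.15. A replicate effect shared by wild type and A4 is thus not excluded. Libraries with different numbers reached 0.231, and wild-type replicate 3 stood at 0.117 with A9 replicate 1. The reported calls come from the fit without pairs, with the replicate block as an alternative.

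Alternatives were a pseudocount of 0.1, no filter, a filter of at least 5 FPKM, median-ratio scaling, quantile normalization, fits of the 2 compared groups, a prior without trend or with a robust fit, a replicate block, FPKM summed per tomato protein, a 2-fold minimum and leaving out each library. Added after seeing the data were sums per assembled gene, loci with a tomato hit, loci of at least 500 bases, lists matched on full descriptions, lists without chance word matches, and leaving out loci near 0 in wild type but expressed in a line. The fit was tested on simulated data for A4 against wild type with 53284 loci, 50 of them changed at each size. It recovered 24% of loci changed 1.5-fold, 40% at 2-fold, 84% at 4-fold and 90% at 8-fold, with 7 false calls among 53084 unchanged loci. Far fewer loci were changed there than the 17121 called in the data for that comparison. The adjusted threshold is stricter when few loci change, so these shares do not give the recovery in the data. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.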

Results

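RNA from the flower corollas of Petunia hybrida cultivar Mitchell, a white-flowered scented petunia, was sequenced in 9 libraries from 3 genotypes. The groups were wild type and lines A4 and A9, both described by the submitters as overexpressing a site-directed mutant of PhADT. Arogenate dehydratase (ADT) forms phenylalanine from arogenate, the closing step of phenylalanine synthesis in plastids, and its proteins are usually annotated as prephenate dehydratases. Each group had 3 libraries. Each sample held at least 8 corollas, taken at 20 h on day 2 after flower opening, while the lights were on from 6 in the morning to 9 in the evening. The values were FPKM of 94534 loci on assembled contigs, of which 79813 had a best match among tomato proteins. The tests covered 53284 loci with a mean of at least 1 FPKM, from 24463 assembled genes and 12909 tomato proteins, so a gene was often measured as several loci that share reads. The depth recovered from the steps of low values was 30800000, 32800000 and 31100000 fragments in wild-type replicates 1, 2 and 3. It was 41700000, 30700000 and 41300000 in the libraries labelled A4 and 35100000, 43100000 and 31900000 in those labelled A9. At the median locus, 1 FPKM stood for between 42.5 and 60.3 fragments. Values below are mean FPKM ± SD over 3 libraries, and changes are on the log2(FPKM + 1) scale, which understates the change of low loci.

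The libraries separated by genotype before any test. Correlations of log2(FPKM + 1) across loci, which are not independent replicates, lay between 0.971 and 0.985 within a group and between 0.881 and 0.943 across groups. The first principal component held 50.4% of the variance and placed wild type at one end, A9 in the middle and A4 at the other end. The second held 27.2% and set A9 apart.

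**Figure D1:**
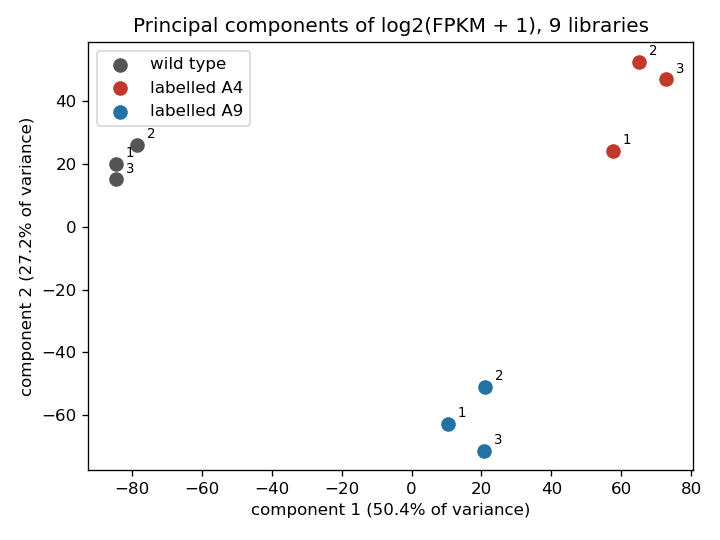
First and second principal components of log2(FPKM + 1) over the 53284 tested loci; each point is a library, coloured by its label and numbered by replicate. The 3 groups do not overlap, and the axes hold 50.4% and 27.2% of the variance.

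The overexpressed gene was examined first, as a check of the labels. In A9, 5 loci matching a tomato prephenate dehydratase rose from wild-type means of at most 0.974 FPKM. XLOC_018765 stood at 0.0130 ± 0.0225 FPKM in wild type and at 95.3 ± 13.8 FPKM in A9, a log2 change of 6.56 (SE 0.10, adjusted p = 1.61e-09). XLOC_018769, XLOC_018770, XLOC_018771 and XLOC_018772, from the same assembled cluster, rose to between 24.7 and 36.5 FPKM in A9. In the libraries labelled A4, XLOC_018765 was at 0.0290 ± 0.0290 FPKM, and none of the 15 measured dehydratase loci rose. With a pseudocount of 0.1, XLOC_018769 and XLOC_018771 passed the threshold in those libraries with log2 changes of 0.40 and 0.37, at 1.18 and 0.681 FPKM. The abundant dehydratase loci were lower there: XLOC_053181 fell from 1721 ± 227 FPKM in wild type to 1105 ± 82.4 FPKM (log2 change -0.63, SE 0.12, adjusted p = 0.00394), and XLOC_053180 and XLOC_053182 fell by 0.65 and 0.73 on the log2 scale. XLOC_053180 missed the threshold after quantile normalization (adjusted p = 0.0706). XLOC_053181 was at 1601 ± 147 FPKM in A9 (adjusted p = 0.599 against wild type).

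Summed over the 15 dehydratase loci, the level was 3464 ± 564 FPKM in wild type, 2203 ± 175 FPKM in the libraries labelled A4 and 3464 ± 335 FPKM in A9. XLOC_053179, XLOC_053180, XLOC_053181 and XLOC_053182, at 640.9, 766.6, 1721 and 309.9 FPKM in wild type, held most of it. XLOC_053179 is 289 bases long, within the range of the 275 to 290 bases subtracted from the locus length in the depth estimate. Its FPKM, from 399.6 to 789.6 in wild type, is thus uncertain, and so is its part in the sum. The sum was not tested without it. The loci that rose in A9 stood at 24.7 to 95.3 FPKM there, little beside the wild-type SD of the sum. The equal sum in A9 therefore says little about their rise. The difference between the 6 libraries of both lines and the 3 wild-type libraries, -630.4 FPKM, did not pass the test (exact two-sided permutation p = 0.238 over 84 splits, of which the smallest possible p is 0.0119). That test pools lines with different levels. Each library labelled A4, from 2089 to 2404 FPKM, lay below each wild-type library, from 2911 to 4038 FPKM; this comparison, added after the sums were seen, gave an exact two-sided permutation p = 0.1 over 20 splits, the smallest that 3 libraries against 3 allow. The label of A4 as an overexpressor was thus not matched by a rise of any annotated dehydratase locus in the reported fit, and directions drawn from those libraries rest on the label. Loci of the same cluster share reads, so their separate levels are uncertain. The calls of the low dehydratase loci XLOC_031410, XLOC_031411, XLOC_031413 and XLOC_031414, lower in the libraries labelled A4, did not hold: without wild-type replicate 1 their adjusted p were 0.1, 0.108, 0.0969 and 0.0527, without wild-type replicate 3 they were 0.0805, 0.111, 0.0955 and 0.0832, and without A4 replicate 3 they were 0.0712, 0.0879, 0.094 and 0.0867. Under median-ratio scaling the calls of XLOC_031410, XLOC_031411 and XLOC_031413 were also lost (adjusted p of 0.0607, 0.0551 and 0.0506), and each of the 4 loci missed the threshold without at least 1 further library. In the reported fit XLOC_031410 and XLOC_031413 were also lower in A9 (adjusted p of 0.00817 and 0.022), whereas XLOC_031411 and XLOC_031414 were not called (0.172 and 0.074). For the mean of both lines the 4 loci were called lower (adjusted p from 0.00694 to 0.0443).

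**Figure D2:**
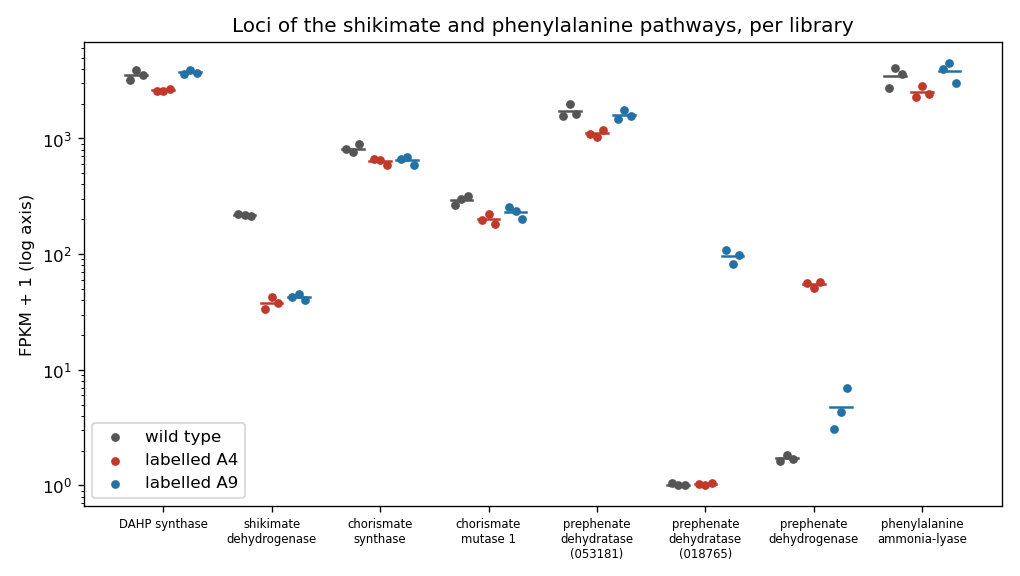
FPKM + 1 on a log axis for 8 loci of the shikimate and phenylalanine pathways, chosen after their values were seen; points are libraries and bars are group means of 3. Dehydratase XLOC_018765 is at 95.3 FPKM in A9 and near 0 elsewhere, shikimate dehydrogenase XLOC_003144 falls from 217 to 37.1 and 41.8 FPKM, and prephenate dehydrogenase XLOC_019220 is at 54.2 FPKM in the libraries labelled A4.

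In the comparison of the libraries labelled A4 with wild type, an expansin, pectate lyases and a 3-ketoacyl-CoA synthase were among the largest rises, and the shikimate pathway and photosynthesis lists were called lower by camera. Neither call held with an estimated correlation (adjusted p of 0.794 and 0.957), and the shikimate call was lost after summing loci per tomato protein (0.16). An expansin, XLOC_012211, of a family that loosens cell walls, rose from 0.247 ± 0.326 to 202.0 ± 35.4 FPKM. A 3-ketoacyl-CoA synthase for very long chain fatty acids, XLOC_083896, rose from 0.981 ± 0.259 to 175.9 ± 41.4 FPKM. Shikimate dehydrogenase XLOC_003144 fell from 217.0 ± 4.83 to 37.1 ± 4.75 FPKM. Of the 53284 loci, 17121 changed (adjusted p under 0.05), 8295 up and 8826 down; 4013 of them changed at least 2-fold, 2657 up and 1356 down. The balance of directions depended on the setting: 9147 rose and 7534 fell under median-ratio scaling, 14522 and 11090 without a filter, and 3020 and 4771 at a mean of at least 5 FPKM.

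The largest rise over all loci in the libraries labelled A4, chosen after its values were seen, was that of XLOC_086678, which has no tomato match (log2 change 10.61, SE 0.13). Among the loci that the naming rule allows, with an informative tomato match, the largest rises were those of XLOC_049909, a fragment named after a rice locus (2.45 ± 3.02 to 1181 ± 319 FPKM, log2 change 8.73, SE 0.59), and of the CONSTANS-LIKE 4 zinc finger XLOC_009171 (1.24 ± 1.90 to 328.7 ± 109.9 FPKM, log2 change 7.46, SE 0.60). A small ubiquitin-related modifier, XLOC_001971, rose from 0.0861 ± 0.149 to 95.0 ± 7.38 FPKM. Pectate lyase 1-27 XLOC_000979, which cleaves pectin, rose from 0.0284 ± 0.0492 to 53.2 ± 9.50 FPKM. A further pectate lyase, XLOC_000988, was listed at 0 in each wild-type library and stood at 51.8 ± 0.838 FPKM. That locus and the F-box locus XLOC_029408 named below are 262 and 241 bases long. This is shorter than the 275 to 290 bases subtracted from the locus length in the depth estimate, so their FPKM are uncertain. The lipid-transfer protein XLOC_030790 reached 72.0 ± 9.29 FPKM and the major latex-like protein XLOC_086331 68.7 ± 10.3 FPKM. A locus described as a viral genome polyprotein, XLOC_091087, was at 92.3 ± 87.3 FPKM against 0.0211 ± 0.0170 FPKM. The largest falls under the same rule were those of the F-box protein XLOC_029408 (31.2 ± 4.94 FPKM in wild type, listed at 0 in each library labelled A4), xyloglucan endotransglucosylase/hydrolase 8 XLOC_070595 (489 ± 283 to 23.9 ± 29.8 FPKM), importin beta-3 XLOC_030025 (200.6 ± 19.2 to 6.47 ± 0.762 FPKM), the wound induced protein XLOC_015559 (40.2 ± 13.1 to 1.42 ± 0.388 FPKM), ethylene responsive factor 1a XLOC_048840 (28.4 ± 5.07 to 0.855 ± 0.299 FPKM) and the flavanone 3-hydroxylase-like XLOC_010253 (56.7 ± 19.3 to 3.02 ± 1.70 FPKM). The kelch F-box protein XLOC_086470, the virus-induced protein variant XLOC_052377 and the membrane protein XLOC_079308 fell by 3.52, 3.31 and 3.28 on the log2 scale. Fasciclin-like protein 4, XLOC_028406, fell by 3.57, but its call was lost without wild-type replicate 1 or 3 or A4 replicate 2 or 3, with adjusted p between 0.0811 and 0.0855.

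The shikimate pathway supplies chorismate for all aromatic amino acids. Of the 88 loci of its list, 41 fell in the libraries labelled A4, 4 rose and 43 did not pass. Adjusted over the list alone, 42 fell and 4 rose. Without chance word matches 79 of the 88 loci remain. The 4 members with the lowest p, XLOC_003144, XLOC_003146, XLOC_003149 and XLOC_003145, were loci of the same assembled shikimate dehydrogenase gene, with log2 changes between -2.53 and -2.23. By assembled gene, 9 of 21 in the list held a fall and 1 a rise. The list was called lower (camera adjusted p = 6.1e-07), with adjusted p = 0.794 with an estimated correlation and 0.16 after summing loci per tomato protein. Outside the naming rule and chosen after its values were seen, DAHP synthase XLOC_040680, the entry enzyme, fell from 3560 ± 359 to 2615 ± 44.6 FPKM, and chorismate synthase XLOC_073766 from 817 ± 68.7 to 632 ± 37.7 FPKM. In the phenylalanine and tyrosine branch 17 of 38 loci fell and 4 rose (17 and 4 adjusted over the list alone, camera adjusted p = 0.221). The median was negative (-0.16) and the mean positive (0.20). By assembled gene, 4 of 15 held a fall and 3 a rise. The loci that rose, also chosen after their values were seen, were 4 prephenate dehydrogenase loci of the tyrosine side. Among them XLOC_019220 rose from 0.715 ± 0.0933 to 54.2 ± 3.68 FPKM and XLOC_019222 from 0.957 ± 0.145 to 38.2 ± 5.98 FPKM. Chorismate mutase 1 XLOC_046360 fell from 294.5 ± 25.5 to 200.1 ± 20.5 FPKM.

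Downstream of phenylalanine, 48 of 121 general phenylpropanoid and monolignol loci fell in the libraries labelled A4 and 14 rose (51 and 15 adjusted over the list alone; camera adjusted p = 0.00468). That list had adjusted p = 0.794 with an estimated correlation and 0.412 after quantile normalization. A cinnamoyl-CoA reductase-like locus, XLOC_062262, fell from 7.29 ± 1.09 to 0.0786 ± 0.136 FPKM, whereas a hydroxycinnamoyl transferase, XLOC_019764, rose from 0.351 ± 0.0378 to 6.60 ± 0.166 FPKM. The abundant phenylalanine ammonia-lyase XLOC_082237, chosen after its values were seen, stood at 3470 ± 674 FPKM in wild type and 2518 ± 297 FPKM in the libraries labelled A4 (adjusted p = 0.0926). Of 33 loci for volatile benzenoids and phenylpropenes, 14 fell and 10 rose (14 and 14 adjusted over the list alone, camera adjusted p = 0.647). The falls came from 2 of 11 assembled genes and the rises from 6, so by gene the balance turned. Aromatic amino acid decarboxylase XLOC_046369 fell from 1567 ± 179 to 732 ± 38.3 FPKM. Of 55 flavonoid and anthocyanin loci, 14 rose and 7 fell (the same counts adjusted over the list alone; camera adjusted p = 0.536), among them chalcone synthase XLOC_042715 (0.864 ± 0.165 to 6.80 ± 0.941 FPKM).

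Of 132 photosynthesis loci, 55 fell in the libraries labelled A4 and 11 rose (62 and 13 adjusted over the list alone) in this marker list for green tissue, with a median log2 change of -0.41 (camera adjusted p = 0.000692; adjusted p = 0.957 with an estimated correlation); chlorophyll a-b binding protein 3C-like XLOC_038904 fell from 88.3 ± 1.52 to 20.9 ± 4.67 FPKM. Of 105 circadian clock loci, 38 fell and 10 rose (49 and 10 adjusted over the list alone; camera adjusted p = 0.00468, 0.794 with an estimated correlation). The clock loci with the lowest p went apart: a LATE ELONGATED HYPOCOTYL locus, XLOC_090666, rose from 0.176 ± 0.0347 to 3.12 ± 0.470 FPKM, and pseudo-response regulator 9, XLOC_001909, fell from 3.36 ± 1.07 to 0.709 ± 0.0580 FPKM. Auxin loci rose more often than they fell, 102 against 58 of 375 (108 and 66 adjusted over the list alone), with camera adjusted p = 0.041 and 0.794 with an estimated correlation. At a mean of at least 5 FPKM the auxin list turned direction (adjusted p = 0.835). Its call was lost without a filter (0.0665), in a fit of the 2 groups (0.0517), and without wild-type replicate 2, A4 replicate 1 or A9 replicate 1 (adjusted p of 0.0566, 0.178 and 0.0504). GH3-like XLOC_074327, of the family that conjugates auxin, fell from 329.9 ± 24.3 to 190.2 ± 11.8 FPKM. With FPKM summed per tomato protein, 1 list, photosynthesis, was called in the libraries labelled A4, and the phenylpropanoid, clock and auxin lists each had adjusted p = 0.494. Defence loci were not called as a list (camera adjusted p = 0.536; 24 rose and 19 fell of 111, 24 and 20 adjusted over the list alone), although PR-1 XLOC_042151 rose from 0.400 ± 0.280 to 29.8 ± 8.94 FPKM and defensin XLOC_030466 from 15.6 ± 2.22 to 91.9 ± 8.32 FPKM. In the jasmonate list 37 of 102 loci fell and 19 rose (43 and 24 adjusted over the list alone, camera adjusted p = 0.158). By assembled gene, 15 of 54 held a fall and 16 a rise. Allene oxide synthase XLOC_060231 rose from 0.411 ± 0.120 to 24.0 ± 3.39 FPKM.

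**Figure D3:**
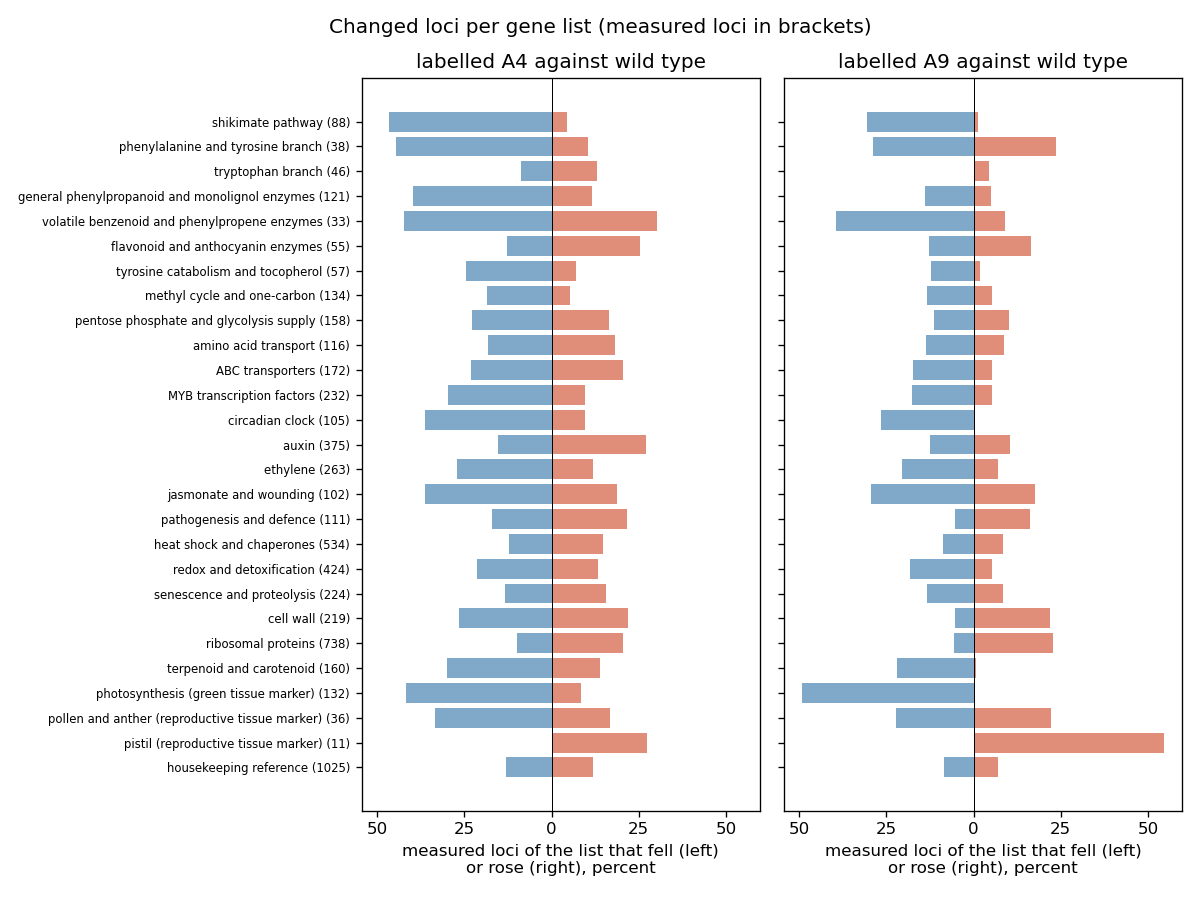
Percent of the measured loci of each gene list that rose (right) or fell (left) against wild type at an adjusted p under 0.05, for the libraries labelled A4 and A9; measured loci are in brackets. Among the 132 photosynthesis loci 55 fell in A4 and 65 in A9, and among the 88 shikimate loci 41 and 27. Loci of the same assembled gene are counted separately.

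In the comparison of A9 with wild type, the dehydratase loci described above rose, shikimate dehydrogenase fell, and camera called the photosynthesis list lower and the ribosomal protein and cell wall lists higher. With an estimated correlation the adjusted p of these 3 lists were 0.326, 0.581 and 0.581, and under fry, which does not compare a list with other genes, ribosomal proteins and cell wall had 0.0675 and 0.113. Shikimate dehydrogenase XLOC_003144 was at 41.8 ± 2.43 FPKM (log2 change -2.35, SE 0.10, adjusted p = 7.44e-07). Chlorophyll a-b binding protein 3C-like XLOC_038904 fell to 27.5 ± 5.70 FPKM. In all, 10253 loci changed, 4786 up and 5467 down, and 2551 changed at least 2-fold, 1661 up and 890 down. Under median-ratio scaling 5236 rose and 4895 fell, and without a filter 7389 and 7280, so the balance of directions turned. The count fell to 6826 without wild-type replicate 1, 6544 without wild-type replicate 3 and 6791 without A9 replicate 3.

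In A9 too XLOC_086678 rose furthest of all loci (log2 change 10.09, SE 0.13). Among the loci that the naming rule allows, the largest rises after XLOC_018765 were those of the small ubiquitin-related modifier XLOC_001971 (100.9 ± 5.89 FPKM), XLOC_049909 (179.6 ± 108.9 FPKM) and CONSTANS-LIKE 4 XLOC_009171 (103.7 ± 72.6 FPKM), all of which also rose in the libraries labelled A4. A fragment named after another rice locus, XLOC_075143, rose from 0.830 ± 0.880 to 77.3 ± 38.8 FPKM. A mitotic checkpoint kinase, XLOC_049057, was listed at 0 in all libraries of wild type and of those labelled A4 and was at 38.0 ± 11.6 FPKM in A9. That locus and XLOC_094322, XLOC_082773 and XLOC_029408, named below, are 230, 260, 230 and 241 bases long. This is shorter than the 275 to 290 bases subtracted from the locus length in the depth estimate, so their FPKM are uncertain. Loci from mobile elements were among the rises: the Pol polyprotein XLOC_094322 was listed at 0 in wild type and was at 32.7 ± 3.54 FPKM, the Pro-Pol polyprotein XLOC_093883 rose from 0.645 ± 0.388 to 29.5 ± 3.05 FPKM, and the tnp2 transposase XLOC_082773 from 4.75 ± 8.23 to 62.2 ± 3.87 FPKM. These mobile-element loci also rose in the libraries labelled A4, to 25.1, 25.3 and 53.9 FPKM. They were not called between the lines (adjusted p of 0.178, 0.436 and 0.89). The largest falls under the same rule were those of importin beta-3 XLOC_030025 (to 7.46 ± 0.447 FPKM), the flavanone 3-hydroxylase-like XLOC_010253 (to 3.00 ± 1.70 FPKM), a cytochrome P450, XLOC_038674 (94.6 ± 15.7 to 8.53 ± 4.66 FPKM), G protein alpha subunit XLOC_088747 (30.5 ± 2.79 to 2.40 ± 1.61 FPKM), glutaredoxin XLOC_019891 (15.8 ± 1.18 to 0.690 ± 0.208 FPKM) and the multidrug resistance protein XLOC_070105 (16.4 ± 5.56 to 1.02 ± 0.296 FPKM). The wound induced protein XLOC_015559, the F-box protein XLOC_029408, the UDP-glucosyltransferase XLOC_093966 and the 3-ketoacyl-CoA synthase XLOC_062597 fell by 2.86, 2.85, 2.83 and 2.72 on the log2 scale.

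In A9, 27 of 88 shikimate loci, from 5 of 21 assembled genes, fell and 1 rose (32 and 5 adjusted over the list alone). The list had camera adjusted p = 0.000131, 0.572 with an estimated correlation and 0.268 after summing loci per tomato protein. In the phenylalanine and tyrosine branch 11 of 38 loci fell and 9 rose (19 and 9 adjusted over the list alone, camera adjusted p = 0.898). The median was negative (-0.32) and the mean positive (0.52). The rises include the 5 dehydratase loci described above, whose log2 changes of 4.09 to 6.56 raise the mean. By assembled gene, 3 of 15 held a fall and 5 a rise. Of 132 photosynthesis loci 65 fell and 0 rose (80 and 0 adjusted over the list alone), with a median log2 change of -0.57 (camera adjusted p = 7.86e-14). Ribosomal protein loci rose, 168 of 738 against 42 that fell (224 and 49 adjusted over the list alone; camera adjusted p = 1.21e-07), and so did cell wall loci, 48 of 219 against 12 (51 and 13 adjusted over the list alone; camera adjusted p = 0.00407). None of these 3 calls held with an estimated correlation (adjusted p of 0.326, 0.581 and 0.581). Of the 105 clock loci 28 fell and 0 rose (35 and 0 adjusted over the list alone), and of 160 terpenoid and carotenoid loci 35 fell and 1 rose (37 and 1 adjusted over the list alone). The clock falls came from 5 of 25 assembled genes and the terpenoid and carotenoid falls from 18 of 58. Those lists had camera adjusted p of 2.53e-06 and 4.94e-05, and adjusted p of 0.326 and 0.572 with an estimated correlation. A carotenoid isomerase-like locus, XLOC_076933, fell from 8.18 ± 0.937 to 2.41 ± 0.119 FPKM in A9 and was at 7.49 ± 0.273 FPKM in the libraries labelled A4.

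The redox list (77 of 424 fell, 22 rose; camera adjusted p = 0.000105), the ethylene list (54 of 263 fell, 18 rose; 0.0066), the MYB list (41 of 232 fell, 12 rose; 0.00822), the ABC transporter list (30 of 172 fell, 9 rose; 0.00851) and the jasmonate list (30 of 102 fell, 18 rose; 0.0109) were also called lower in A9. Adjusted over the list alone, the falls numbered 82, 66, 41, 32 and 36 and the rises 23, 24, 13, 9 and 19. In the reported calls the falls came from 49, 29, 22, 8 and 10 assembled genes. The rises came from 20, 17, 8, 6 and 13, so by gene the jasmonate balance turned. With an estimated correlation the adjusted p were 0.411, 0.326, 0.326, 0.572 and 0.581. ACC oxidase XLOC_068581, the ethylene-forming enzyme, fell from 5.32 ± 1.02 to 0.717 ± 0.138 FPKM in A9 and to 0.578 ± 0.0395 FPKM in the libraries labelled A4. The tyrosine catabolism list (7 of 57 fell, 1 rose, as when adjusted over the list alone; camera adjusted p = 0.0202) and the pistil marker list (6 of 11 rose, 0 fell, 6 and 1 adjusted over the list alone; 0.0395) had adjusted p of 0.572 and 0.326 with an estimated correlation. Without A9 replicate 2 both missed the threshold (adjusted p = 0.104 for each), as did the jasmonate list (0.0776). Without wild-type replicate 3 the tyrosine list missed it (0.0575), and without A9 replicate 3 the ABC transporter list (0.0505). Without a filter the MYB, ethylene and ABC transporter lists had adjusted p of 0.474, 0.137 and 0.0547. At a mean of at least 5 FPKM the clock, ethylene, jasmonate and pistil lists had 0.138, 0.0696, 0.138 and 0.236, and the tyrosine list 0.964 with its direction turned. With FPKM summed per tomato protein, 4 lists were called in A9: photosynthesis, ribosomal proteins, cell wall, and terpenoids and carotenoids. A pistil extensin-like locus, XLOC_040054, rose from 43.2 ± 7.07 to 76.5 ± 5.17 FPKM in A9.

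Loci changed in both lines included shikimate dehydrogenase, cathepsin B-like proteinase and a cellulose synthase, all lower. Cathepsin B-like XLOC_005160, a protein-degrading enzyme, fell from 54.9 ± 1.71 to 7.13 ± 0.205 FPKM in the libraries labelled A4 and to 13.2 ± 0.251 FPKM in A9. Cellulose synthase XLOC_066908 fell from 8.24 ± 0.433 to 0.369 ± 0.0653 and 0.207 ± 0.0225 FPKM. Methionine synthase XLOC_024673, of the methyl cycle, fell from 1690 ± 88.8 to 1128 ± 77.6 and 1185 ± 103.4 FPKM. The amino acid permease XLOC_077290 fell from 5.79 ± 0.177 to 1.24 ± 0.155 and 1.66 ± 0.443 FPKM, and 6-phosphogluconate dehydrogenase XLOC_015787 from 18.7 ± 1.60 to 6.94 ± 0.439 and 6.74 ± 0.969 FPKM. The plastid isoprenoid enzyme DXP synthase 1, XLOC_030992, fell from 12.8 ± 0.689 to 5.34 ± 0.766 and 5.79 ± 0.579 FPKM, and 40S ribosomal protein S24, XLOC_085405, rose from 42.3 ± 0.819 to 135.3 ± 20.6 and 130.9 ± 41.4 FPKM.

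For the mean of both lines against wild type, 15573 loci changed, 7565 up and 8008 down (8424 up and 6943 down under median-ratio scaling), and 10 of 27 lists were called by camera, 0 of them with an estimated correlation. In both single comparisons 6788 loci changed the same way, 3077 up and 3711 down (3410 and 3228 under median-ratio scaling), and 124 changed in opposite directions. Independent lists of those sizes would share 745 higher and 906 lower loci. Unchanged groups simulated against the same wild-type libraries in 50 runs had a median of 0 calls in each line, so their shared count of 0 sets no level for the overlap. The log2 changes of both lines correlated at 0.674 across loci, against 0.5 for simulated unchanged groups, and their covariance was 0.244 against 0.0167. Part of the overlap may come from the shared wild-type libraries, of which 3 are too few to split; without wild-type replicate 3 the shared count was 4419.

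Between the lines, an expansin, a pectate lyase and a bZIP factor were higher in the libraries labelled A4, and dehydratase loci, a xyloglucan endotransglucosylase/hydrolase and a heat shock protein were higher in A9. Expansin XLOC_012211 was at 202.0 ± 35.4 FPKM in the libraries labelled A4 and 7.15 ± 1.86 FPKM in A9 (log2 difference 4.65, SE 0.22, adjusted p = 2.61e-06). Pectate lyase 1-27 XLOC_000979 was at 0.757 ± 0.318 FPKM in A9, the 3-ketoacyl-CoA synthase XLOC_083896 at 11.3 ± 5.10 FPKM, and the bZIP factor XLOC_083380 at 27.9 ± 10.8 FPKM in those labelled A4 and 1.01 ± 0.492 FPKM in A9. Higher in A9 were XLOC_018765, the checkpoint kinase XLOC_049057, the Phi-1 protein XLOC_064369 (77.6 ± 77.6 against 1.245 ± 1.192 FPKM), the heat shock protein XLOC_065348 (55.0 ± 38.4 against 1.35 ± 0.502 FPKM) and XTH 8 XLOC_070595 (509 ± 323 against 23.9 ± 29.8 FPKM). The call of XLOC_070595 was lost without A4 replicate 3 (adjusted p = 0.0502). In all, 9614 loci differed, 5280 higher in the libraries labelled A4 and 4334 higher in A9 (1954 and 2445 at a mean of at least 5 FPKM, where the balance turned). The count was 5457 without A4 replicate 2, 4912 without A4 replicate 3, 5944 without A9 replicate 1 and 6141 without A9 replicate 3. Of 27 lists 8 were called by camera and 0 with an estimated correlation. The cell wall list, with a median difference of -0.22 (A4 minus A9), was not called without the replicate block (camera adjusted p = 0.0954) and had adjusted p = 0.0222 with it, 0.0198 at a mean of at least 5 FPKM and 0.0224 without A4 replicate 1. Without the block its adjusted p was 0.997 with an estimated correlation, and under fry it was 0.987 with the opposite direction.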

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

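The tests of the A4 label, of RNA from another organism and of loci without a match were chosen only after the result was seen. Groups of 3 libraries are too small for a test of single outlying libraries. Results are listed here because the effect of A4 and that of A9 against the same wild type differed by the test of A4 against A9, at an adjusted p under 0.05. That held for 9614 loci and for 71 of the 149 named loci. The naming rule took some loci because they differed between the lines or were extreme in a line. The share among named loci is thus partly set by that choice.

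Of the dehydratase loci, XLOC_018765, XLOC_018769, XLOC_018770, XLOC_018771 and XLOC_018772 differed by -6.54, -4.03, -4.13, -3.93 and -3.99 on the log2 scale (A4 minus A9), and XLOC_053180, XLOC_053181 and XLOC_053182 by -0.56, -0.53 and -0.65. Among the other loci, the differences were 5.84 for the viral-type polyprotein XLOC_091087, 4.95 for pectate lyase XLOC_000979, 4.65 for expansin XLOC_012211, 3.90 for XLOC_083896 and 3.81 for the bZIP factor XLOC_083380. They were -5.24 for the checkpoint kinase XLOC_049057, -4.81 for Phi-1 XLOC_064369, -4.79 for XTH 8 XLOC_070595 and -4.38 for the heat shock protein XLOC_065348. The lists called between the lines had small median differences: -0.13 for the shikimate pathway, -0.14 for general phenylpropanoid enzymes, 0.11 for ABC transporters, 0.11 for auxin, 0.08 for redox, -0.13 for ribosomal proteins, 0.07 for terpenoids and 0.22 for photosynthesis. Their camera adjusted p lay between 0.0136 and 0.0432, and between 0.582 and 0.997 with an estimated correlation.

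No annotated dehydratase locus rose in the libraries labelled A4 in the reported fit, though 2 low loci passed with a pseudocount of 0.1. The libraries labelled A4 were unlike the wild-type libraries: their highest correlation with a wild-type library was 0.902, below the lowest within a group, 0.9707. That separation was known before the test was chosen, and the replicates may be technical. The test therefore cannot exclude that other wild-type samples stand under a wrong label. However, 67 loci were below 0.5 FPKM in every wild-type library and at least 5 FPKM in every library labelled A4 or A9. A further 25 loci showed the reverse. These values, shared by A4 and A9, argue against wild-type samples under the A4 label, for those loci, which were defined by their values. Transgene reads may have been counted on a locus without a tomato match, and 3 such loci were below 0.5 FPKM in each wild-type library and at least 100 FPKM in every library of both lines. The most abundant, XLOC_086678, was at 1757, 2006 and 2584 FPKM in A4 and 1459, 1445 and 1462 FPKM in A9. What these loci encode was not analysed here, so this explanation, a silenced transgene and a difference between the lines stay open.

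The polyprotein locus XLOC_091087 stood at 31.0, 53.7 and 192.3 FPKM in A4 replicates 1, 2 and 3, and at most at 0.339 FPKM elsewhere, and a further locus with the same description, XLOC_004860, at 4.24, 9.08 and 16.6 FPKM and at most at 0.123 FPKM elsewhere. RNA of another organism, such as a virus, may be their source, which cannot be told apart from an effect of the genotype. The highest A4 library was 6.20 times the lowest for the first locus and 3.90 times for the other, but only 6 other loci with a tomato match were found in A4 alone, with a median ratio of 1.28, too few to compare with, and the levels had been seen before the test was chosen. Whether the level of this RNA set the size of the other A4 changes cannot be told apart, since over 5882 loci the median ratio of the effect in replicate 3 to that in replicate 1 was 1.252, with quartiles of 1.013 and 1.557. An A4 effect of the transgene stays open and was not tested apart from it.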

How the results depend on the processing

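Tests added after seeing the data are the sums per assembled gene, the restricted sets of loci and the other ways of matching lists. Counts below are in the order A4 with wild type, A9 with wild type, mean of both lines, A4 with A9, and the same way in both lines. At a mean of at least 5 FPKM they were 7791, 4833, 7053, 4399 and 3250, fewer loci being tested. With FPKM summed per tomato protein they were 5799, 3810, 5299, 3643 and 2517, and per assembled gene 9144, 5914, 8505, 5558 and 3893, again over fewer units. With at least a 2-fold change they were 4013, 2551, 2929, 2084 and 1662. All other settings with every library kept stayed within 1.5 times. Leaving out each library in turn gave 12526 to 17228, 6544 to 10073, 10706 to 14706, 4912 to 8903 and 4419 to 6068 loci; with 2 libraries left in a group, that group is assumed to vary like the others. Depth limits the low loci, as 1 FPKM is about 42.5 fragments at the median locus in the shallowest library.

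The number of lists called moved more, and except for the coarser units the cause was not tested. In the order A4 with wild type, A9 with wild type, mean of both lines and A4 with A9, camera with an estimated correlation called 0, 0, 0 and 0 lists. FPKM summed per tomato protein gave 1, 4, 4 and 0, and sums per assembled gene 1, 6, 3 and 3. Fry called 8 in A4 with wild type and 4 in A4 with A9. Without a filter 4 lists were called in A4 with A9, quantile normalization gave 6 for the mean and 4 for A4 with A9, full descriptions gave 6 for the mean, and leaving out loci near 0 in wild type gave 8 for A4 with wild type. Leaving out each library gave 4 to 7, 10 to 13, 7 to 10 and 3 to 8 lists. A4 with A9 gave 3 without A4 replicate 1, 5 without A4 replicate 2, 3 without A9 replicate 2 and 4 without A9 replicate 3.

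Among list results called in the reported test, under the alternative or in both, 5 reversed direction, the cause not being tested. Directions that differed with no call on either side are not counted. At a mean of at least 5 FPKM, the auxin list in A4 (adjusted p = 0.835), tyrosine catabolism in A9 (0.964) and the clock between the lines (0.0243) turned. Under fry, the phenylalanine and tyrosine branch turned in A9 (0.000303) and in the mean of both lines (0.00214), where its median and mean differ in sign. That list holds the 5 dehydratase loci that rose in A9, by 4.09 to 6.56 on the log2 scale. The list was not tested without them. Of the single-locus results with all libraries kept, 1850 stayed as they were, called or not called. A call was lost in 9 and gained in 3, and no direction of a named locus called on either side reversed. The dehydratase sum did not pass the test in any setting run, with differences from -906.4 to -343.3 FPKM over the libraries left out, with permutation p between 0.107 and 0.571, and p = 0.333 with the replicate block. With the replicate block the counts were 18489, 11773, 16953, 11128 and 7739. The block ended the call of XLOC_031411 and brought that of XLOC_053179 in A4 with wild type, where the numbers were not taken to pair the samples. It also called ribosomal proteins there (0.0366) and tyrosine catabolism for the mean (0.0227). Tyrosine catabolism for the mean was at 0.0976 in the reported test and 0.768 with an estimated correlation, and also passed without a filter (0.00442) and under fry (0.0315). The ribosomal list in A4, at 0.0502 in the reported test and 0.957 with an estimated correlation, also passed with a pseudocount of 0.1 (0.0447), at a mean of at least 5 FPKM (0.000297), under median-ratio scaling (0.0415) and quantile normalization (0.00199), in a fit of the 2 groups (0.0469) and without a trend (0.0475). Beyond the cell wall list between the lines the block changed no other call of a list or named locus. Over all loci, 9657 of the 10253 calls for A9 and 8979 of the 9614 between the lines were shared with the block. Of the 9 libraries 6 correlated best with their own number, a hint from the data and not the design.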

Other observations

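No test here was chosen only after its result was seen, though the loci near 0 in wild type were noticed in the data first. Further members of the gene lists, taken by the naming rule, had these values. The salicylic acid carboxyl methyltransferase XLOC_033515 rose from 0.0464 ± 0.0804 FPKM in wild type to 10.7 ± 2.78 FPKM in the libraries labelled A4 and 4.88 ± 3.83 FPKM in A9. The anthocyanidin glucosyltransferase XLOC_065945 rose from 0.0195 ± 0.00065 to 10.5 ± 2.48 and 0.905 ± 0.147 FPKM, while the anthocyanin acyltransferase-like XLOC_029374 fell from 43.5 ± 3.95 to 15.6 ± 2.40 and 12.9 ± 2.31 FPKM. The S-adenosylmethionine synthase XLOC_014000 was at 7.16 ± 1.81 FPKM in wild type, 7.68 ± 0.121 FPKM in A4 and 23.2 ± 2.44 FPKM in A9. Jasmonate ZIM-domain protein 3, XLOC_036119, fell from 6.47 ± 0.159 to 4.23 ± 0.210 and 3.74 ± 0.200 FPKM.

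In 67 loci every wild-type library was below 0.5 FPKM and every library of both lines at least 5 FPKM, and 25 loci showed the reverse. Of the gained loci 65.7% and of the lost loci 44% had no tomato match, against 11.8% of all tested loci, and 18 gained loci and 1 lost locus matched mobile-element proteins. Of the 46 gained loci that were long enough, 97.8% still met the definition after thinning the line libraries to the depth of the shallowest wild-type library. The depths were close and these loci stood at 5 FPKM or more, so the thinning could hardly remove them and says little. A4 replicate 2, at 30700000 fragments, was already shallower than each wild-type library, from 30800000 to 32800000, and was not thinned. Every gained locus was at least 5 FPKM there. That argues against lower depth of the wild-type libraries for those loci but does not exclude it, and the near-0 values in wild type were not tested. Sequence variants of a gene assembled as separate contigs may contribute and cannot be told apart from other causes: 44.6% of the loci had a locus called in the opposite direction in their assembled cluster, against a median of 31.5% and a highest value of 44.6% over 1000 matched sets. A change of expression caused by the transgene was not tested.

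Other splits of the libraries bear on the counts. For the mean of both lines the real split gave 15573 changed loci, a count reached by 1 of 100 drawn splits (of 840), the real one itself. The next was 15069, from a split that kept each genotype whole. Splits mixing genotypes had a median of 0 and a highest count of 8390. The share thus shows that libraries of a genotype are alike, as the principal components did. It cannot show that the difference of both lines from wild type is more than a difference between any of these genotypes, since another whole-genotype split came close. For loci changed the same way in both lines the values were 6788 and 5884, again 1 of 100. For the lists called in the mean of both lines, 17 of 100 splits gave at least the real 10, up to 16, so chance is not excluded. The comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. Their real counts were 17121, 10253 and 9614 for A4 with wild type, A9 with wild type and A4 with A9, as many as 1 split each, and the highest other counts were 1, 0 and 0. In the last 2 comparisons, where the numbers were taken to pair the libraries, 4 of the 10 splits part all pairs, and the others of these gave at most 0 calls, as did the rest. The lists called were 5, 13 and 8, with 10, 10 and 13 as the highest of other splits, and 6, 1 and 3 splits gave as many.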
